A study of Caenorhabditis elegans with 3 samples.

How the data were processed

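Whole young adult worms of the fem-1 strain were treated by feeding RNA interference, their RNA was extracted with TRIZOL and TruSeq poly(A) libraries were sequenced on a HiSeq2000, per the labels' protocols. The 3 libraries, 1 per group (mock, dcr-1 knockdown, drsh-1 knockdown), were assigned by their titles and by the genotype the submitters gave. The table that the authors deposited holds whole-number read counts per gene, not normalized, for 20287 genes in 3 columns, each matched by name to 1 library. Every entry names a gene. CASAVA 1.8.2, STAR, HTSeq and edgeR are listed in the submitters' processing notes, without further settings. The genome build, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here, so no coordinates are printed. Without a stated strand, a gene and an overlapping or antisense partner cannot be told apart. Members of near-identical families (major sperm proteins, vitellogenins, collagens, pals genes, F26F2 genes, actins) are uncertain where reads could be split between copies.

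Of the 20287 gene names, 15504 were current symbols, 3723 were sequence names matched to a current gene and 1060 had no match and were kept as given. Names came from the gene tables of the WBcel235 assembly, used for names only. Genes are written by current symbol where one exists, except C40A11.10, which keeps the name given in the table. In all 3 libraries, 1922 entries (9.47%) were at 0, among them 50 of 77 ribosomal protein genes and the vitellogenins vit-2, vit-5 and vit-6. Ribosomal protein genes are abundant in any worm library, and the measured vitellogenins were abundant in these. An entry at 0 in all libraries is therefore treated as not measured, and other entries may hold only part of a gene's reads. The cause was not tested.

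Library totals were 9044041 (mock), 10519917 (dcr-1) and 9950859 (drsh-1). Scaling factors were taken from all 3 libraries by the TMM method in edgeR 4.0.16 (0.985, 1.09 and 0.928 in the same order) under R 4.3.3. Ratios were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Genes with a mean of at least 1 CPM over the libraries were tested, 13067 in number. For each pair of libraries the log2 ratio of scaled counts was taken with a prior count of 0.5, and the 95% interval of the ratio came from the exact conditional binomial (Clopper-Pearson) interval of the counts. A gene was counted as higher or lower when the log2 ratio was at least 1 in size and the interval excluded 1. With 1 library per group no residual degrees of freedom remain, so the quasi-likelihood test of edgeR could not be fitted and no p-value was computed. Folds and their intervals are given without a prior count. Against 0 counts, the fold is a bound taken against 3 counts in that library and is printed as at least that value. It takes the other count as exact, so it can lie above the lower end of the 95% interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The procedure was tested on simulated counts with known folds, where intervals held the true ratio for 95.6% of genes (dcr-1 against mock), 95.4% (drsh-1 against mock) and 96.0% (dcr-1 against drsh-1).

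The 24 gene lists, the rule for the genes named, the thresholds and the alternatives were fixed before the data were examined. The lists, written from general knowledge, cover the microRNA machinery, the RNA interference and secondary small RNA machinery, reported microRNA targets, reported 26G targets, microRNA genes, the intracellular pathogen response, antimicrobial effectors, heat shock and the unfolded protein response, oxidative stress with xenobiotic and DAF-16 associated genes, vitellogenins, collagens, molting, oocyte, germline, sperm, zygotic embryo, intestine, muscle, hypodermis, neurons, vulva with uterus and gonadal sheath, and, for RNA quality, histones, mitochondrially encoded genes and ribosomal proteins. Lists share some members. The list of microRNA genes had 0 entries, which leaves 23 lists. For each list the median log2 ratio of the measured members was set against 10000 random lists of the same size, matched in 20 bins of mean CPM, and its percentile describes these libraries only. No percentile was taken for the vitellogenins, with 3 measured members.

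The genes named were the 10 highest and 10 lowest in each comparison against mock and the 5 highest and 5 lowest in the direct comparison, ranked by the interval bound nearest to 1, up to 4 members of each list per comparison, and dcr-1, drsh-1, pash-1, alg-1, alg-2, lin-41, hbl-1, lin-14, lin-28 and daf-12 in any case. From the 207 genes this gave, those that carry each comparison are printed. The exceptions, chosen after their values were seen, are pals-25, unc-129, ccf-1 and eol-1.

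The alternatives were DESeq2 size factors (DESeq2 1.42.0), total counts and upper-quartile scaling in place of TMM, no filter (at least 1 count) or a mean of at least 5 CPM, a 3-fold threshold, an interval entirely beyond 2-fold, a prior count of 5, and Spearman's rho in place of Pearson's r. Gene families of at least 10 tested members were scanned by the stem of their symbols, and the genes apart in each comparison of simulated unchanged libraries were counted, steps added after the data were seen.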

Results

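Poly(A) RNA was sequenced from young adult Caenorhabditis elegans of the fem-1 strain, a background described as sterile, with oocytes but no sperm of its own. Whether each culture was sterile could not be checked here. The animals were fed bacteria that deliver double-stranded RNA. They formed 3 groups, a mock treatment, a knockdown of dcr-1 and a knockdown of drsh-1, with 1 library in each. Dicer, encoded by dcr-1, cuts double-stranded RNA and microRNA precursors, and Drosha, encoded by drsh-1, cuts primary microRNA transcripts before Dicer does. The series asks how Dicer bears on the transcripts it binds, with the Drosha knockdown and the mock treatment as controls, in worms and in human cells. The human samples were not analysed here. The libraries held 9044041 counts for the mock treatment, 10519917 for the dcr-1 knockdown and 9950859 for the drsh-1 knockdown, and at least 1 count was recorded for 16536, 17305 and 16807 genes. A count of 0 allowed up to 0.337, 0.261 and 0.325 CPM (counts scaled by library size) in the same order, which is 3 counts. There are no replicates, so each comparison is one of libraries and not of conditions, no difference has a replicate check, and no p-value is given. Intervals and floors cover counting error only.

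The targeted genes were read first. The library of the dcr-1 knockdown held 1133 counts of dcr-1, or 98.5 CPM, against 2082 counts and 234 CPM in the mock library, which is 2.37-fold lower (95% counting interval 2.20 to 2.55). The library of the drsh-1 knockdown held 711 counts of drsh-1 against 1574 counts in the mock library, which is 2.29-fold lower (0.398 to 0.476 as a ratio to mock). Each target was therefore lower in the library that carries its name, although transcripts of both remained. In the other knockdown, dcr-1 held 1732 counts in the drsh-1 library, 1.25-fold below mock (1.17 to 1.33), and drsh-1 held 1783 counts in the dcr-1 library, 1.14-fold below mock (1.06 to 1.22). Fragments of the double-stranded RNA that was fed may be counted on these genes. The transcript of pash-1, the partner of Drosha, differed little, at 1.14-fold lower (1.06 to 1.22) in the dcr-1 library and 1.08-fold higher (1.01 to 1.16) in the drsh-1 library.

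**Figure D1:**
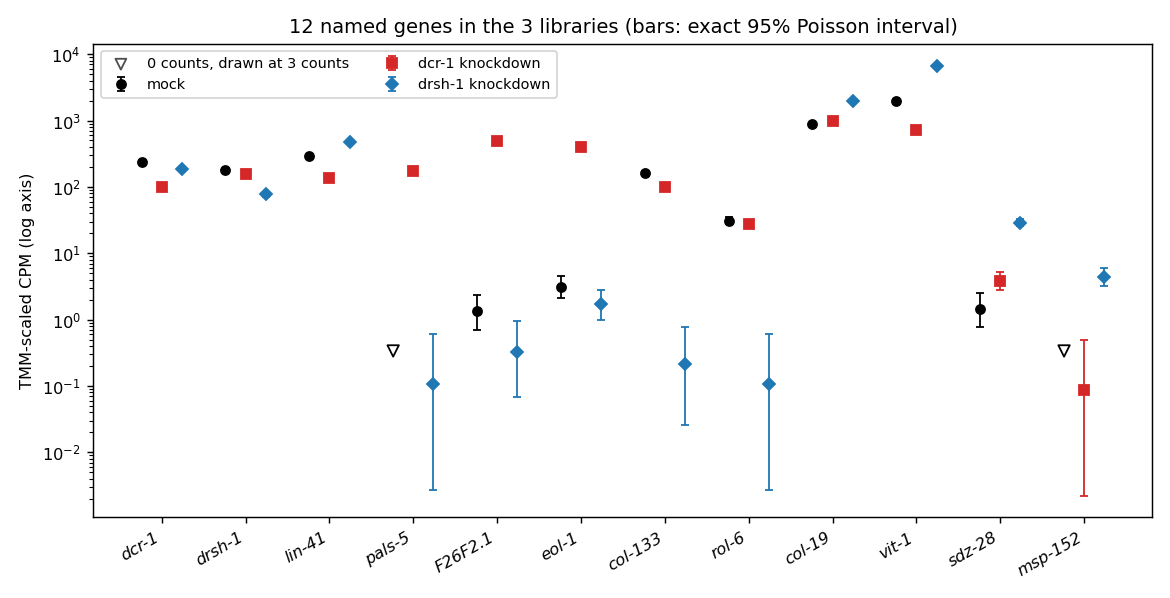
Scaled CPM of 12 genes in the mock (black circles), dcr-1 (red squares) and drsh-1 (blue diamonds) libraries on a log axis, with exact 95% Poisson intervals; open triangles mark 0 counts, drawn at 3 counts. The targets dcr-1 and drsh-1 are lowest in their own knockdown, pals-5, F26F2.1 and eol-1 (the last chosen after its values were seen) are highest in the dcr-1 library, and col-133 and rol-6 are lowest in the drsh-1 library.

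The dcr-1 knockdown was set against the mock treatment first. Genes of the intracellular pathogen response, the programme that worms mount against microsporidia and the Orsay virus, differed most. Of 35 measured members of that list, 34 were at least 2-fold higher in the dcr-1 library with an interval that excluded 1, and 0 were lower. Their median log2 ratio was 6.07 (quartiles 3.67 and 8.49), and the list took 0.658% of all counts in the dcr-1 library against 0.0309% in the mock library. The reporter gene of the programme, pals-5, had 2016 counts in the dcr-1 library and 0 in the mock library and was at least 521-fold higher. The related pals-3 and pals-29 were at least 368-fold and 355-fold higher, and F26F2.1 was 367-fold higher (209.7 to 710.01). The Skp1-related gene skr-5, which codes for a part of ubiquitin ligases, was 2.73-fold higher (2.26 to 3.31), and pals-26 was 11.3-fold higher (8.74 to 14.9). The exception was pals-25, a regulator of the programme named here after its values were seen, which was 1.88-fold higher (1.39 to 2.57) and stayed under the 2-fold threshold.

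Ranked over all genes by the interval bound nearest to 1, the highest genes included members of this list and genes outside it. F26F2.2 had 3984 counts against 0 and was at least 1029-fold higher, F26F2.4 had 4129 counts against 1 (3200.1-fold, 574 to 126428), and pals-11 had 2597 counts against 0 and was at least 671-fold higher. C43D7.4 was at least 420-fold higher, and F42C5.3 was 322-fold higher (163 to 746). The F26F2 genes, the pals genes and other tandem families hold similar copies, so the share of each member is uncertain. At the other end, C32H11.4 was 13.8-fold lower (0.0607 to 0.0854 as a ratio to mock), Y39B6A.1 6.04-fold lower (5.36 to 6.81) and the acyltransferase-like gene oac-32 7.01-fold lower (5.22 to 9.58). The acid sphingomyelinase gene asm-3 was 5.88-fold lower (4.56 to 7.66), the glucocerebrosidase gene gba-4 4.34-fold lower (3.82 to 4.94), the cytochrome P450 gene cyp-14A2 6.67-fold lower (3.56 to 13.6) and the C-type lectin genes clec-186 and clec-53 were 4.12-fold (3.74 to 4.56) and 4.81-fold (3.33 to 7.12) lower.

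Defence and stress genes outside that programme did not share 1 direction. Of 44 antimicrobial and innate immune effectors, 8 were higher and 15 lower in the dcr-1 library, or 10 and 10 with scaling by total counts (median log2 ratio −0.57, percentile 0 among 10000 random lists of matched expression). The lectin gene clec-60 was 22.7-fold higher (16.9 to 31.2), the lysozyme gene ilys-3 6.85-fold higher (3.76 to 13.7) and clec-42 had 190 counts against 20, whereas dod-24 was 3.54-fold lower (3.32 to 3.78). Of 22 heat shock and unfolded protein response genes, 6 were higher and 0 lower (median 0.55, percentile 100), among them the small heat shock genes hsp-12.6 at 10.3-fold (6.88 to 15.9) and hsp-16.41 at 2.20-fold (1.99 to 2.43), and the protein disulfide isomerase gene pdi-2 at 2.14-fold (1.93 to 2.37). Of 34 oxidative stress, xenobiotic and DAF-16 associated genes, 3 were higher and 8 lower, or 5 and 5 with scaling by total counts (median −0.18, percentile 2.61), with cyp-35A2 at 2.99-fold lower (0.279 to 0.399 as a ratio) and dod-3 at 4.30-fold lower (3.69 to 5.04). The vitellogenins, which encode yolk proteins, were lower in all 3 measured members, with ratios to mock of 0.374 (0.365 to 0.384) for vit-1, 0.437 (0.425 to 0.449) for vit-3 and 0.355 (0.345 to 0.365) for vit-4. Reads of vit-3 and vit-4 may be exchanged between these near-identical copies.

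Small RNA pathways were compared next. Of 19 genes reported as targets of 26G small interfering RNAs, which depend on Dicer and the Argonaute ERGO-1, 5 were higher and 0 lower in the dcr-1 library, or 9 and 0 with scaling by total counts, with a median log2 ratio of 0.88 (quartiles 0.41 and 1.17, percentile 100). C40A11.10 had 69 counts against 8 and K06B9.6 had 43 against 6, R03H10.6 was 2.19-fold higher (1.77 to 2.74) and T08B6.2 2.62-fold higher (1.39 to 5.31). Of 30 reported microRNA targets, 1 was higher and 3 were lower (median 0.0023, percentile 28.6). That list was written from general knowledge and may hold genes, mab-10 among them, that microRNAs affect only indirectly. The heterochronic gene lin-41, a let-7 target that oocytes also express, was 2.17-fold lower (2.04 to 2.32), mab-10 2.20-fold lower (1.61 to 3.04) and lin-42 2.01-fold lower (1.48 to 2.74). With scaling by total counts, lin-41, mab-10 and lin-42 fell short of the 2-fold threshold. The higher member was unc-129, at 2.02-fold (1.52 to 2.71), named here after its values were seen. The split of the list was 0 higher and 3 lower with DESeq2 size factors and 2 and 0 with total counts. The others named in advance lay within 2-fold, with lin-14 at 1.36-fold lower (1.06 to 1.74), daf-12 at 1.30-fold lower (1.08 to 1.56), lin-28 nearly equal, with 1840 counts against 1433, and hbl-1 at 1.19-fold higher (0.745 to 1.91). Of 24 genes of the microRNA machinery, the target dcr-1 itself was lower and 0 were higher (median −0.11, percentile 54.6). The microRNA Argonaute genes alg-1 and alg-2 had ratios of 1.06 (0.924 to 1.22) and 1.66 (1.20 to 2.33). Of 40 genes of the RNA interference and secondary small RNA machinery, the RNA-dependent RNA polymerase gene rrf-2 was higher at 2.62-fold (2.24 to 3.08) and the sperm Argonaute gene alg-3 lower, with 1 count against 11 (14.2-fold, 2.06 to 611; median of the list −0.23).

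Markers of tissues and germ cells were read next. No cuticle collagen of 55 was counted in either direction (median −0.18), and of 28 molting genes 0 were higher and 2 lower (median 0.025, percentile 23.5), the latter being wrt-2 at 2.80-fold (1.56 to 5.19) and lin-42. Of 35 oocyte and eggshell genes, cey-3 was 2.48-fold higher (1.72 to 3.66) and lin-41 lower (median −0.35, percentile 3.75). Of 43 germline proliferation and meiosis genes, only rnr-2 was higher at 2.49-fold (1.79 to 3.51; median −0.29, percentile 3.16). Of 32 sperm genes, 1 was higher and 2 lower, msp-81 with 0 counts against 7 and alg-3. The median of that list was −0.87, or −0.76 with members at 0 counts set to their bound (percentile 0), and most members had few counts. Of 19 zygotic embryo genes, sdz-26 was 3.80-fold higher (1.90 to 8.41), sdz-28 2.62-fold higher (1.39 to 5.31) and ref-1 2.14-fold lower (1.55 to 2.99), a split of 3 and 0 with scaling by total counts (median 0.11, percentile 35.9). Muscle genes were higher in 5 of 28 (median 0.19, percentile 99.3), such as tnt-2 at 2.20-fold (1.61 to 3.05) and unc-97 at 2.20-fold (1.65 to 2.98). Of 14 intestinal genes, 1 was higher and 2 lower (median 0.18, percentile 99.8), the latter cpr-6 at 2.31-fold (2.25 to 2.37) and ftn-1 with 479 counts against 829. Of 19 hypodermal and seam genes, hch-1 and grd-10 were 4.42-fold (2.24 to 9.70) and 2.28-fold (1.87 to 2.79) higher and wrt-2 lower (median −0.15, percentile 8.90). Of 41 neuronal genes, unc-46 was 5.68-fold higher (1.71 to 29.7; median 0.026), and of 20 genes of vulva, uterus and gonadal sheath none was counted (median 0.10, percentile 51.7). Of the lists kept for RNA quality, mitochondrially encoded genes had a median of 0.68 (12 members, 1 higher, percentile 100), histones −0.16 (17 members, 0 counted, percentile 3.86) and ribosomal proteins −0.22 (9 members, 0 counted, percentile 27.7).

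Over the 13067 genes tested, 974 were higher and 327 lower in the dcr-1 library by at least 2-fold with an interval excluding 1, and 70.9% of genes lay within 1.5-fold. Of the 1301 genes apart, 74.9% were higher. Scaling by total counts moved the median log2 ratio of all genes from 0.013 to 0.16 and the share of higher genes to 86.9%. In data simulated for this comparison with counting noise alone, 96% of genes set 3-fold apart and 100% of those set 8-fold apart were recovered, and 76 unchanged genes of a run over 13067 were counted. Unchanged libraries simulated with the dispersion of the 3 libraries gave 3841 genes apart in this comparison on average, more than the 1301 observed. That dispersion is 1 value for all genes and contains any effect of the knockdowns, so this simulation cannot decide whether there was one. Without replicates, the number of genes apart is not read as evidence of an effect.

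**Figure D2:**
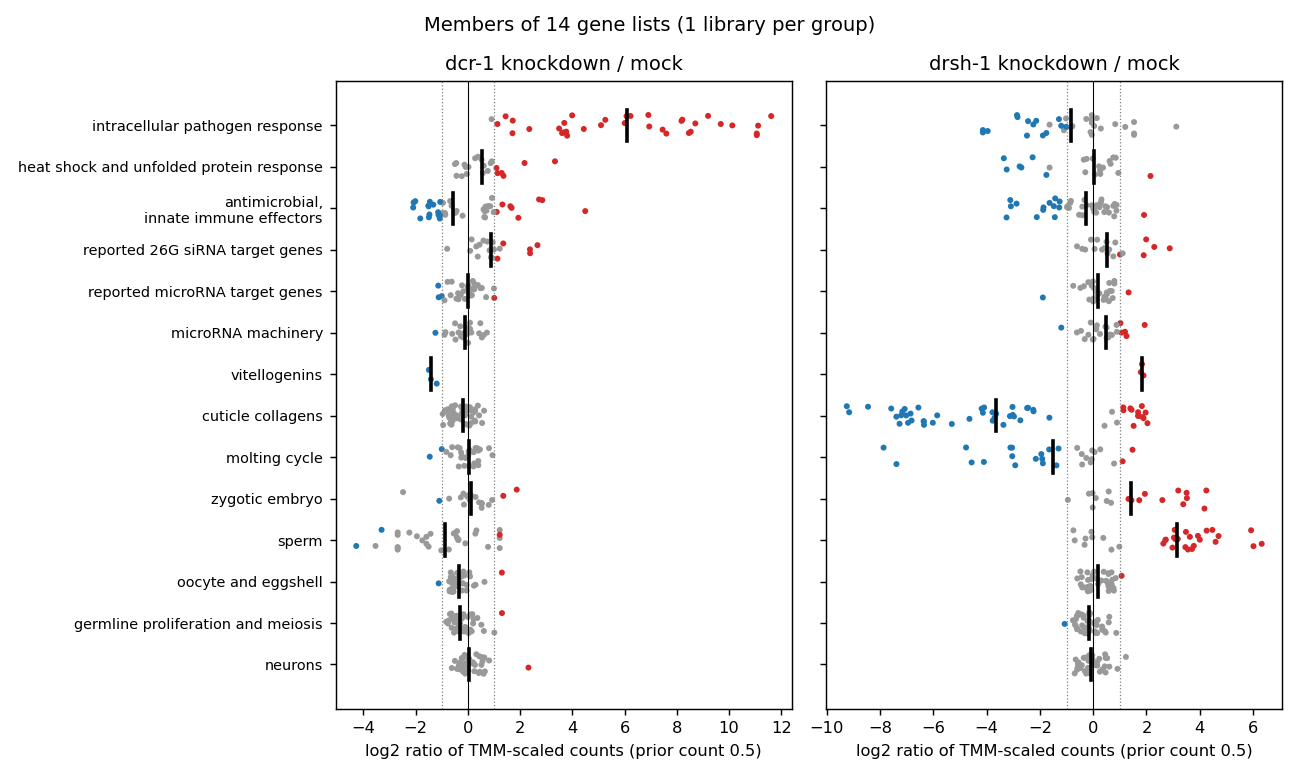
Log2 ratios of TMM-scaled counts for each measured member of 14 gene lists, dcr-1 knockdown against mock (left) and drsh-1 knockdown against mock (right), with 1 library per group. Points in red were counted as higher, in blue as lower and in grey as neither, black bars are medians and dotted lines mark a 2-fold ratio; the intracellular pathogen response has a median of 6.07 on the left and −0.84 on the right, and cuticle collagens −0.18 and −3.64.

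The drsh-1 knockdown was set against the same mock library, as the comparison in which microRNA processing is targeted upstream of Dicer. Its library held far less transcript of most cuticle collagens. Of 55 members, 39 were lower and 13 higher, with a median log2 ratio of −3.64 (quartiles −6.46 and 0.80, percentile 0). The roller collagen rol-6 had 1 count against 276 (286-fold lower, 50.9 to 11341), col-133 had 2 against 1463 (758-fold lower, 209.5 to 6268) and sqt-3 had 32 against 570 (18.5-fold lower, 12.9 to 27.3). The adult cuticle collagen col-19 was instead 2.19-fold higher (2.13 to 2.25), and the summed share of the list was larger in the drsh-1 library, at 3.63% of counts against 1.62%. Of 28 molting genes, 16 were lower and 2 higher (median −1.52, quartiles −3.04 and −0.084, percentile 0), including ptr-4 at 19.2-fold lower (7.18 to 72.2), wrt-6 with 4 counts against 102, and grl-5 and grl-21, hedgehog-related genes with 0 counts that were at least 38.7-fold and 27.6-fold lower. Vitellogenins were higher in all 3 measured members, vit-1 by 3.45-fold (3.39 to 3.51), vit-3 by 3.56-fold (3.50 to 3.62) and vit-4 by 3.70-fold (3.64 to 3.77).

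Genes of sperm and of early embryos were higher in the drsh-1 library. Of 32 sperm genes, 23 were higher and 0 lower (median log2 ratio 3.13, quartiles 0.91 and 3.95, percentile 100). The major sperm protein gene msp-152 had 41 counts against 0 and was at least 13.2-fold higher, msp-33 had 62 against 2 (29.9-fold, 7.94 to 252) and msp-36 had 74 against 5 (14.3-fold, 5.85 to 45.3). All these levels are low, the msp genes are near-identical copies, and among sperm genes with a mean of at least 5 CPM the median turned to −0.065. Genes such as msp-152 reached a mean of 1 CPM only through the drsh-1 library, so the filter fixed their direction. Of 19 zygotic embryo genes, 11 were higher and 0 lower, or 11 and 1 with scaling by total counts (median 1.44, percentile 100), with sdz-28 at 19.7-fold (11.3 to 37.4), pes-10, one of the first genes transcribed in the embryo, at 10.9-fold (5.54 to 24.6), the T-box gene tbx-38 with 76 counts against 6 and vet-6 at 6.10-fold (4.41 to 8.63). Of 35 oocyte and eggshell genes, only cyb-3 was higher, with 1097 counts against 505, and with scaling by total counts none was counted (median 0.18, percentile 97.2), and of 43 germline proliferation and meiosis genes only nos-1 was lower, with 618 counts against 1253 (median −0.15).

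Ranked over all genes by the interval bound nearest to 1, the lowest genes included many collagens. F41F3.3 had 0 counts against 1625 and was at least 562-fold lower, col-161 and col-175 were at least 373-fold and 320.3-fold lower, rol-1 at least 195-fold lower and col-145 at least 132-fold lower. The collagens col-73 and col-77 were 547-fold (187 to 2657) and 175-fold (94.9 to 365) lower. Reads shared between collagen copies make the level of single members uncertain. The highest by the same rank included sdz-4, with 75 counts against 1, sdz-9, with 96 against 3, nsph-3.2, with 73 against 2 (35.2-fold, 9.40 to 296), F34D6.1, with 70 against 2, and sepa-1, an autophagy substrate of the early embryo, at 13.7-fold (9.34 to 20.9). F26D2.16, ins-31 and F53C3.11 had 0 counts in the mock library and were at least 14.1-fold, 13.5-fold and 12.9-fold higher.

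In the small RNA pathways, 5 of 24 genes of the microRNA machinery were higher in the drsh-1 library and 1, drsh-1 itself, was lower (median 0.48, percentile 100). The Argonaute gene alg-2 was 3.84-fold higher (2.85 to 5.26), alg-1 2.03-fold (1.79 to 2.31), the DEAD-box helicase gene cgh-1 2.38-fold (2.31 to 2.45), vig-1 2.09-fold (2.02 to 2.15) and the deadenylase gene ccf-1, named here after its values were seen, 2.29-fold (1.87 to 2.83). With scaling by total counts alg-1 and vig-1 fell short of the threshold. Of 30 reported microRNA targets, die-1 was 2.52-fold higher (2.01 to 3.16) and lin-42 3.75-fold lower (0.173 to 0.400 as a ratio; median 0.19, percentile 91.2). lin-41 was 1.62-fold higher (1.54 to 1.70), lin-14 1.74-fold higher (1.41 to 2.15), daf-12 1.42-fold higher (1.21 to 1.68), hbl-1 1.36-fold higher (0.843 to 2.21) and lin-28 1.39-fold lower (1.29 to 1.51), all short of the threshold. Of 19 reported 26G targets, 5 were higher and 0 lower (median 0.53, percentile 99.1), among them C40A11.10 at 7.72-fold (3.69 to 18.6) and F39F10.4 at 4.97-fold (3.25 to 7.89). No gene of 40 in the RNA interference machinery was counted (median −0.19, percentile 8.17), and eri-1, which limits small RNA silencing, was 1.82-fold lower (1.69 to 1.97).

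Part of the intracellular pathogen response was lower in the drsh-1 library, with 14 of 35 members lower, 0 higher and 21 neither (median −0.84, quartiles −2.01 and −0.0068, percentile 0). Here skr-5 was 7.31-fold lower (0.0811 to 0.219 as a ratio), pals-6 5.51-fold lower (3.76 to 8.31) and B0507.8 7.88-fold lower (3.10 to 25.6). Some members had few counts in the mock library, such as pals-5 with 0 and F26F2.1 with 12, which leaves little room for a decrease. The pals family, scanned after the data were seen, had 6 of 31 genes lower, 1 higher and 24 neither (median −0.052). Of 44 antimicrobial effectors, 13 were lower and 1 higher (median −0.29, percentile 0.04), such as abf-2 at 7.39-fold (5.68 to 9.75) and lys-3 at 9.95-fold lower (5.18 to 21.4). Heat shock genes went both ways, with 6 of 22 lower and 1 higher (median 0.028 but mean −0.52, percentile 57.6). The ratio to mock was 0.105 (0.0811 to 0.134) for hsp-70 and 0.154 (0.119 to 0.196) for hsp-16.2, and hsp-16.41 was 4.85-fold lower (3.96 to 5.98). Of 34 oxidative stress and xenobiotic genes, 8 were higher and 8 lower (median −0.032, percentile 34.2), with the metallothionein gene mtl-2 at 4.24-fold higher (3.72 to 4.84) and cyp-34A9 at 7.12-fold lower (5.92 to 8.63).

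Among tissue markers, 6 of 28 muscle genes were higher and 0 lower, or 3 and 0 with scaling by total counts (median 0.68, percentile 100), for example unc-15, which encodes paramyosin, with 2100 counts against 913. Of 14 intestinal genes, 1 was higher and 4 were lower (median −0.53, percentile 0.03), with acdh-1 at 6.14-fold higher (5.72 to 6.60), and the cysteine protease gene cpr-3 at 8.26-fold lower (7.41 to 9.22), the ferritin gene ftn-1 with 102 counts against 829 and far-3 at 4.24-fold lower (3.87 to 4.64). Of 19 hypodermal and seam genes, 2 were higher and 4 lower, and the latter included rol-6, sqt-3 and wrt-2, which other lists also hold (median 0.000855 but mean −0.81, percentile 45.5). No neuronal gene of 41 was counted (median −0.075, percentile 10.2). Of 20 genes of vulva, uterus and gonadal sheath, lag-2 was 8.80-fold higher (4.24 to 21.2) and lim-7 2.23-fold higher (1.69 to 2.97; median 0.23, percentile 86.1). Mitochondrially encoded genes had a median of 0.73 (2 of 12 higher, percentile 99.98), histones 0.082 (1 of 17 higher and 1 lower, percentile 55.2) and ribosomal proteins 0.36 (2 of 9 higher, percentile 88.8). The mitochondrial list took 0.760% of counts in the mock library, 1.34% in the dcr-1 library and 1.33% in the drsh-1 library. Both knockdowns shared this difference, so it may lie in the mock library, and its cause was not tested.

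Over all 13067 genes tested, 1078 were higher and 1030 lower in the drsh-1 library, which makes 51.1% of the 2108 genes apart higher. The majority turned to lower with scaling by total counts, at 919 higher and 1160 lower, and with upper-quartile scaling, at 1000 and 1085. It also turned to lower with a mean of at least 5 CPM, with a 3-fold threshold and with the interval entirely beyond 2-fold. More than 8-fold lower were 321 genes, against 5 in the comparison of dcr-1 with mock. In data simulated with counting noise alone for this comparison, 95% of genes set 3-fold apart and 100% of those set 8-fold apart were recovered. There, 75 unchanged genes were counted, against 3819 on average in unchanged libraries with the dispersion of the 3 libraries and 2108 observed. The simulation with dispersion again cannot decide whether there was an effect.

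The knockdowns were then compared with each other directly, since the Drosha knockdown serves as a control for the effect of Dicer outside microRNA processing. The intracellular pathogen response was higher in the dcr-1 library for 34 of 35 members and lower for 0 (median log2 ratio 7.78, or 6.98 with members at 0 counts set to their bound). F26F2.4 and F26F2.3 were at least 1106-fold and 869.6-fold higher, F26F2.1 1520.4-fold (519.98 to 7375) and B0507.8 1399-fold (599 to 4310). Outside the list, pals-11 was at least 696-fold higher. Collagens were higher for 39 members and lower for 12, or 39 and 9 with scaling by total counts (median 3.06), and molting genes higher for 16 and lower for 1 (median 1.39). On the lower side, all 3 vitellogenins were lower (median −3.20), as were 25 of 32 sperm genes, with 1 higher (median −4.52, or −4.02 at their bound, but −0.034 among sperm genes with a mean of at least 5 CPM), and 12 of 19 zygotic embryo genes, with 0 higher (median −1.39). Against mock, the medians in the dcr-1 and drsh-1 libraries were −0.18 and −3.64 for collagens and 0.025 and −1.52 for molting genes. They were −0.87 and 3.13 for sperm genes and 0.11 and 1.44 for zygotic embryo genes. For these lists the larger part of the difference therefore lay in the drsh-1 library. In the direct comparison, Y39B6A.1 was 24.8-fold lower in the dcr-1 library, from 338 counts against 6742. nsph-3.2, msp-81 and msp-33 had 0 counts in the dcr-1 library and were at least 30.3-fold, 26.1-fold and 25.7-fold lower, and the sperm gene ssq-4 had 2 counts against 114 (70.9-fold lower, 19.2 to 593).

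Small RNA genes were also compared directly, and their counts depended on the scaling. Of 24 genes of the microRNA machinery, 1 was higher and 7 lower in the dcr-1 library, or 1 and 2 with scaling by total counts (median −0.52, percentile 0.210). Of 30 reported microRNA targets 2 were higher and 5 lower, or 4 and 3 with that scaling (median −0.42), with lin-41 at 3.52-fold lower (3.32 to 3.73). The reported 26G targets did not stand apart, with 2 higher and 2 lower, or 4 and 2 with that scaling (median 0.41), nor did the RNA interference machinery, with 3 higher and 4 lower, or 3 and 1 with scaling by total counts or by the upper quartile (median 0.13, percentile 94.1). Of the remaining lists, antimicrobial effectors were higher for 15 and lower for 15 members (median −0.67), heat shock genes for 8 and 2 (0.20), oxidative stress and xenobiotic genes for 7 and 10 (0.11), oocyte genes for 0 and 5 (−0.48), germline genes for 1 and 3 (0.079), intestinal genes for 5 and 3 (0.75), muscle genes for 0 and 5 (−0.27) and hypodermal genes for 6 and 3 (−0.021). With scaling by total counts the splits in the same order were 17 and 9, 8 and 0, 8 and 8, 0 and 2, 2 and 2, 6 and 3, 0 and 3, and 6 and 1. No neuronal gene was counted, although 5 were higher and 0 lower with scaling by total counts or by the upper quartile (0.18), and the medians were −0.39 for vulva, uterus and gonadal sheath, −0.11 for histones, −0.14 for mitochondrially encoded genes and −0.65 for ribosomal proteins. In all, 1707 genes were higher and 1437 lower, or 54.3% of 3144 higher, and with a mean of at least 5 CPM the majority turned to lower, at 881 higher and 952 lower. Scaling by total counts moved the median of all genes from 0.025 to 0.26 and the share of higher genes to 71.4%, and upper-quartile scaling moved the median to 0.11. With counting noise alone, simulated data for this comparison recovered 96% of genes set 3-fold apart and 100% of those set 8-fold apart. There, 61 unchanged genes were counted, against 3849 on average in unchanged libraries with the dispersion of the 3 libraries and 3144 observed. Here too, the simulation with dispersion cannot decide whether there was an effect.

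**Figure D3:**
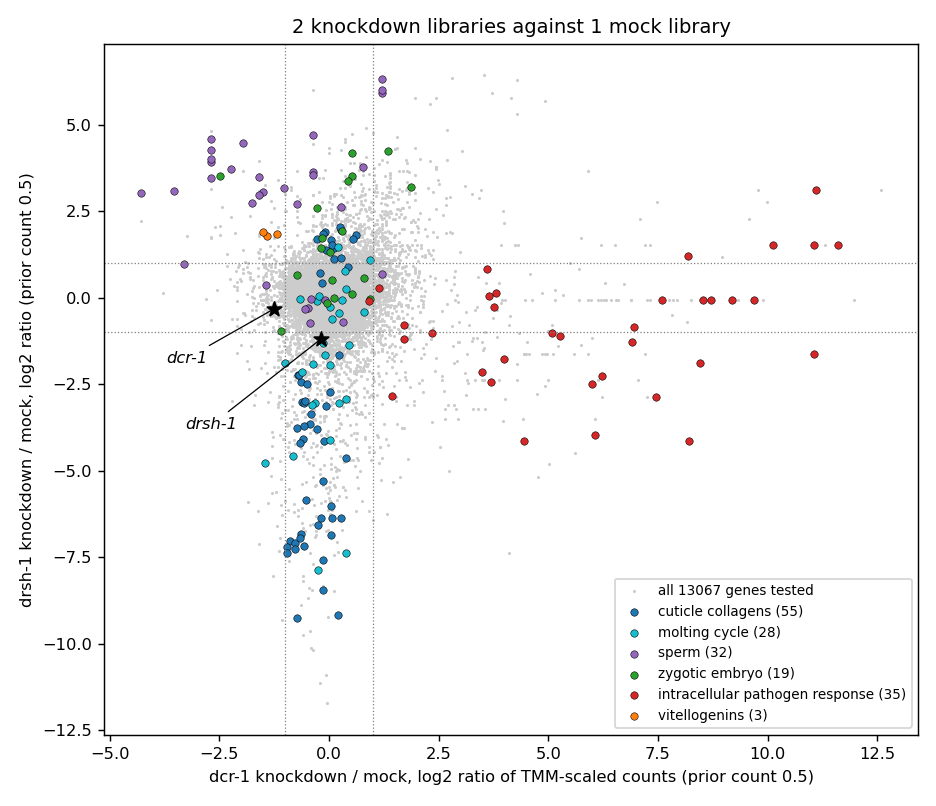
Log2 ratios of TMM-scaled counts of the dcr-1 library (horizontal axis) and the drsh-1 library (vertical axis) to the same mock library for 13067 genes (grey), with 6 gene lists in colour, stars on the targeted genes and dotted lines at 2-fold. Pathogen response genes (35) spread to the right, and collagens (55) and molting genes (28) spread downwards, with r = 0.066 across all genes.

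The profiles of both knockdowns against mock were then compared across genes. Pearson's r over the 13067 genes was 0.066 and Spearman's rho 0.086, with a covariance of 0.0740, where genes are not independent replicates. Because both ratios use the same mock library, 100 simulations of 3 unchanged libraries gave a mean r of 0.536 and a covariance of 0.0399 with counting noise alone, and an r of 0.504 and a covariance of 0.516 with the dispersion of the 3 libraries taken as 1 group. The latter dispersion is 1 value for all genes and contains any effect of the knockdowns. The covariance it gave, 0.516, lay above the 0.0740 observed, so it is not taken as a measure of noise in these libraries. The same 221 genes were higher in both libraries, where independent lists would share 80.4 and the simulations gave 8.23 with counting noise and 846 with dispersion. Another 68 genes were lower in both (25.8 for independent lists, 4.05 and 628 in the simulations). In opposite directions were 156 genes, where independent lists would give 103.75. The mock library cannot be split, so part of any shared direction may come from it.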

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

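No test was run for the pattern in this part. The vitellogenins vit-1, vit-3 and vit-4 went in opposite directions in the knockdowns against the same mock library, with a median log2 ratio of −1.42 in the dcr-1 library and 1.83 in the drsh-1 library. All 3 measured members shared each direction, and the yolk protein genes took 0.526% of counts in the mock library, 0.226% in the dcr-1 library and 1.77% in the drsh-1 library. The difference between the knockdowns was not tested, since each group has 1 library.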

How the results depend on the processing

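No paired analysis was possible because each group has 1 library and shares only 1 number with the others, and no replicate could be left out. For 399 results, 1757 values were recomputed under alternatives fixed in advance. Of these, 1529 stayed within their interval, or within 1.5-fold for a count of genes, 227 moved further (194 of them single named genes) and 1 reversed. Only genes counted as higher or lower, and lists with a median of at least 1 in size, could count as reversed. A smaller value that changed sign within its interval could be among the 1529. Stricter rules lowered the counts of genes by their construction. For dcr-1 against mock, higher and lower genes numbered 382 and 186 with a mean of at least 5 CPM, 423 and 80 with a 3-fold threshold, and 322 and 92 with the interval entirely beyond 2-fold. For drsh-1 against mock they were 498 and 539, 530 and 673, and 506 and 565, and for dcr-1 against drsh-1 881 and 952, 1052 and 529, and 967 and 795. With scaling by total counts, lower genes numbered 194 for dcr-1 against mock and 931 in the direct comparison, and the dcr-1 transcript had a log2 ratio of −1.10 in its own knockdown (−1.25 with TMM). The same scaling gave medians, for dcr-1 against mock, of −0.084 for the RNA interference machinery, −0.032 for collagens, 0.25 for vulva, uterus and gonadal sheath and 0.83 for mitochondrially encoded genes, a median of 1.75 for vitellogenins in drsh-1 against mock, and in the direct comparison 0.37, −2.97, 0.41 and 0.099 for the RNA interference machinery, vitellogenins, neurons and mitochondrially encoded genes. Sperm genes in drsh-1 against mock had a median of 2.2983 with a prior count of 5 and of −0.065 with a mean of at least 5 CPM, the reversed value, and −0.034 in the direct comparison with that filter, which leaves out sperm genes of low count. With that filter r between the knockdowns was −0.0067, and the cause was not tested.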

Other observations

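The gene families in this paragraph were scanned only after the data were seen, over 100 families in each comparison. In the dcr-1 library, F-box and MATH domain families, whose members are often recruited to ubiquitin ligases, held many higher genes. Of 33 math genes 18 were higher and 0 lower (median log2 ratio 1.04), 41 fbxa genes were higher, 2 lower and 86 neither (0.67), and of 81 fbxb genes 27 were higher and 2 lower (0.79). Other families with these domains held fewer, with 6 of 28 fbxc genes higher and 1 lower (0.38) and 3 of 34 bath genes higher and 0 lower (0.055). Insulin-like ins genes were higher for 10 of 22 (1.02). In the drsh-1 library, 74 of 81 fbxb genes and 16 of 23 sdz genes, named for zygotic transcripts that depend on the transcription factor SKN-1, were higher and 0 lower (median log2 ratios 2.5972 and 2.76), as were 17 of 17 msp genes (3.93, or 3.63 with members at 0 counts set to their bound). The direction of msp genes such as msp-152 was fixed by the filter, since they reached a mean of 1 CPM only through the drsh-1 library. Lower there were 75 col genes, with 20 higher and 24 neither (median −3.03, or −2.6021 at their bound), 22 fbxa genes, with 4 higher and 103 neither (−0.35), 13 of 25 nas astacin protease genes, with 2 higher (−1.40), 12 of 14 nspc genes (−1.58), 8 of 15 fipr genes (−2.25) and 8 of 14 grl genes (−1.89, or −1.51 at their bound). Families hold similar copies, so single members are uncertain.

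For the patterns below, the tests of double-stranded RNA feeding, scaling, infection, the last molt and sperm were chosen only after the result, or genes close to it, had been seen, and the tests of heat shock, hypodermal RNA and oocyte RNA were set before.

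Intracellular pathogen response genes were higher in the dcr-1 library (median log2 ratio 6.07). Feeding of double-stranded RNA as such may be argued against as the whole cause, since the drsh-1 library, fed in the same way, had a median of −0.84 (quartiles −2.01 and −0.0068). Some members had few counts in the mock library, so this median is read only as the absence of a rise. The target in the drsh-1 library was not dcr-1, so the drsh-1 library cannot show what feeding does where dcr-1 is lowered. Scaling may also be argued against, since the lowest median over 4 scalings was 6.05. A heat shock or unfolded protein response stays open, with a median of 0.55 (quartiles −0.075 and 1.05) over 22 genes. Infection of the dcr-1 culture by a virus or microsporidium would give the 34 higher members seen, but these members are the pattern itself, so their number cannot decide it. A loss of Dicer, which takes part in antiviral defence, is the other candidate explanation and was not tested. Infection and knockdown cannot be told apart from gene counts with 1 library in the group, and reads of a pathogen were not examined.

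Molting and cuticle genes were lower in the drsh-1 library (molting median −1.52). Scaling is argued against, with a highest molting median of −1.51 over 4 scalings. For less hypodermal RNA, 15 hypodermal and seam genes outside the collagen and molting lists had a median of 0.062 (quartiles −0.27 and 0.38). These values argue against it only as far as those genes mark hypodermis, and how particular they are to that tissue was not tested. Animals further past the last molt would give the vitellogenin median of 1.83 beside the molting median, but these values cannot decide it. The molting median is the pattern itself. In the dcr-1 library, the vitellogenin median was −1.42 against mock while the molting median was 0.025, so vitellogenins also moved without molting genes. Whether such a difference in age came from the culture or from the knockdown of drsh-1, which the design names, was not tested.

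Zygotic embryo genes were higher in the drsh-1 library (median 1.44), in a strain described as sterile. More oocyte RNA is argued against, since 35 oocyte and eggshell genes had a median of 0.18 (quartiles −0.20 and 0.58). Sperm and fertilised embryos in some drsh-1 animals may account for it, as a hypothesis, since 32 sperm genes had a median of 3.13 (quartiles 0.91 and 3.95), although these genes have few counts and the median turned to −0.065 among sperm genes with a mean of at least 5 CPM. All 17 tested msp genes, which are near-identical copies, were higher. The filter fixed the direction of those that, like msp-152, reached a mean of 1 CPM only through the drsh-1 library. Neither their number nor the sperm median that includes them is therefore independent support. Of 10 genes of the spe family, which the sperm list also draws on, 1 was higher and 0 lower (median −0.050). Whether the culture of the drsh-1 library or the knockdown of drsh-1 itself allowed sperm or embryos was not tested.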
